A study of Homo sapiens with 28 samples.

How the data were processed

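DNA methylation was profiled by MBD-seq, in which fragments of genomic DNA that carry methylated CpG sites are captured with the methyl-CpG-binding domain of a protein and sequenced. Enriched stretches (peaks) therefore mark methylated, CpG-containing DNA, and a peak list shows where captured DNA exceeded an uncaptured input, not a methylation level per site. The DNA came from peripheral blood mononuclear cells of 14 persons, each sampled at time point 1 and time point 2, which gives 28 libraries. The groups were 6 control persons without post-traumatic stress disorder (PTSD), 4 persons with increased PTSD and 4 persons with persistent PTSD. The replicate number within a group names the person and pairs the libraries of time points 1 and 2.

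The authors deposited a peak list per library. Per the notes of the authors, reads were checked with FastQC 0.10.1, aligned to the human genome build hg19 with BWA 0.7.8, and peaks were called with MACS2 2.1.0.20140616. Per the file headers, the caller was MACS 2.1.0.20150731 in all 28 lists, each with a q limit of 0.01 against the same input library of 79159269 filtered tags. The deposited positions give the chromosome, the start counted from 1 and the end of each peak. The deposited pileup is a signal in fragments at the summit. The deposited -log10 p and -log10 q come from the test of the peak caller, and the deposited fold enrichment is a ratio of the library to the input at the summit. The notes of the authors also name DiffBind, whose output was not used here. Reads were not analysed here, so counts per region outside the called peaks are unknown and every comparison below rests on where peaks were called.

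Filtered tags per library, per the file headers, ran from 5.54 M to 9.03 M with a median of 6.80 M. The lists held between 17142 and 253806 autosomal peaks, a 14.8-fold range, so the lists were matched in number before any comparison of places. Autosomal peaks of each library were ranked by -log10 p, ties by fold enrichment and then position, and the strongest 17142 were kept, which is the whole of the smallest list. The kept peaks made up between 6.75% and 100% of a list. A region or window without a kept peak is therefore one that held none of the strongest peaks of that library, not one without methylation. Chromosomes X and Y were left out.

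The gene annotation at hand is of another genome build than the peaks. As fixed before the data were examined for that case, windows of 100 kb took the place of genes, and the comparisons of gene lists, promoter peaks, blood cell marker genes, transcription start regions and single genes were not made. Each of 28812 autosomal windows was given the base pairs covered by kept peaks, as log2 of the covered length plus a pseudocount of 200 bp. The 12254 windows covered in at least 7 of the 28 libraries were tested with limma 3.58.1 in R 4.3.3 with a mean-variance trend and Benjamini-Hochberg adjustment at a threshold of 0.05. The changes from time point 1 to 2 within a group, and the differences between groups in that change, were fitted with the person as a block; the differences between groups at a time point were fitted on the 14 libraries of that time point. The text names windows by a rule set before the data were examined. Where fewer than 5 windows passed the threshold, it took the 5 highest and 5 lowest test statistics among windows covered in at least 14 libraries that moved the same way in every person of the group, or whose groups did not overlap, and gives them as not past the threshold. Simulated changes of 200 windows were tested in the same way. A change of 1 on the log2 scale was recovered in 0.50% of them for the change in increased PTSD, a change of 2 in 14.5% and a change of 3 in 76.8%.

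Kept peaks of all libraries were merged into 189039 consensus regions when they overlapped by at least 1 bp. Gains and losses were counted as regions that went from no peak to a peak, or the reverse, in every person of a group, and were set against the same count after every exchange of the time points within persons. Presence was compared between groups with Fisher's exact test per region and Benjamini-Hochberg adjustment. Overlap between libraries was measured as the Jaccard index of covered base pairs, the shared length over the joint length, and the 2 libraries of a person were set against all pairings of time point 1 with time point 2 libraries within groups. Peak numbers, covered lengths and shares were compared with two-sided exact permutation tests, with signs flipped over persons for changes and labels exchanged for groups. The smallest p that these tests allow is 0.125 for a change in 4 persons, 0.0312 for a change in 6, 0.0286 for 4 persons against 4 and 0.00476 for 4 against 6. Correlations over persons used 100000 random permutations.

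Alternatives set before the data were examined were smaller, larger, unmatched and length-matched peak lists, a stricter peak limit of -log10 q of 5, ranking by fold enrichment, another pseudocount, other filters, centring of libraries, other models of the pairing and of the variance, a 50% overlap, and each person left out in turn. Windows of 20 kb and 1 Mb, peak counts per window, covariates for list size and fragment length, and windows away from the longest peak-free stretch of each chromosome were added after the data were seen. Interval operations used bedtools 2.31.1, and the other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.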

Results

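The data were 28 peak lists of methylated DNA from blood mononuclear cells, of 6 control persons, 4 persons with increased PTSD and 4 persons with persistent PTSD at 2 time points. Per the series labels, the study asks how DNA methylation changes in patients with PTSD after an intervention, with the course of PTSD read at time point 2 against time point 1. All positions are on hg19, and no gene annotation of that build was used. Each list rested on between 5.54 M and 9.03 M filtered tags.

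Methylated DNA was captured most densely on the small, gene-rich chromosomes. Chromosome 19 held 19.03 ± 3.01 kept peaks per Mb (SD, n = 28 libraries), chromosome 16 held 13.8 ± 2.06 and chromosome 17 held 12.5 ± 1.74, against 2.95 ± 0.423 on chromosome 3. Chromosome 22 held 11.1 ± 1.72. These densities were taken over the length up to the last peak, peak-free stretches included, which lowers them where such a stretch is long (16.1 Mb on chromosome 22). The shares of length that follow leave out the longest peak-free stretch of each chromosome. Within 5 Mb of the chromosome ends, which make up 7.21% of that length, lay 29.3% ± 2.34 of the kept peaks. Within 2 Mb of the longest peak-free stretch of each chromosome, 2.89% of that length, lay 8.03% ± 0.672. Over all deposited peaks the share was 27.0% ± 2.89 near the ends and 3.70% ± 1.27 near the peak-free stretch, so the latter excess belonged mostly to the strongest peaks. On most chromosomes that stretch is the unassembled block at the centromere. These measures were chosen after the data were seen.

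**Figure D1:**
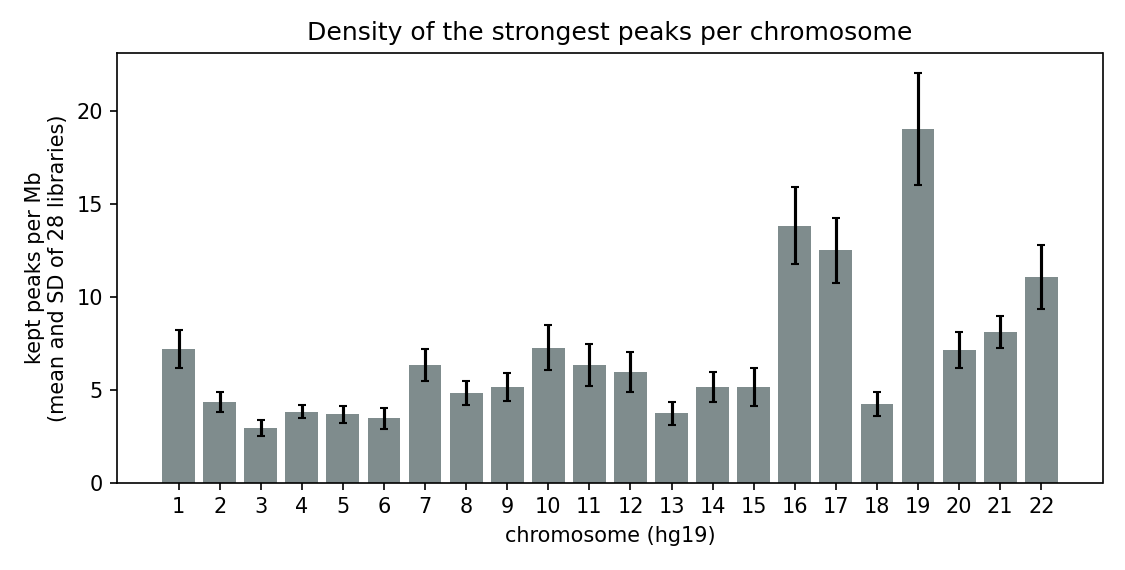
Kept peaks per Mb of each autosome (hg19), as the mean and SD over 28 libraries. Chromosome 19 stood highest at 19.03 peaks per Mb and chromosome 3 lowest at 2.95.

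Few regions were among the strongest peaks of every library. Of 189039 consensus regions, 533 held a kept peak in all 28 libraries, 3566 in at least 14 libraries and 109544 (57.9%) in 1 library. Of the 533 shared regions, 275 (51.6%) lay within 2 Mb of the longest peak-free stretch of their chromosome. The strongest shared region was on chromosome 3 from 75716862 to 75722031, followed by chromosome 10 from 135477845 to 135499139 next to the end of the long arm. Others lay beside the centromere of chromosome 10, from 42384060 to 42388721, and of chromosome 16, from 46397157 to 46410123. Strength here is the mean rank by -log10 p against the same input library, not a methylation level. No stretch of the autosomes was left out here for poor mapping to the reference. Whether mapping or methylation places these regions among the strongest was not tested.

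The number of peaks called per library differed 14.8-fold. Control persons had 135666 ± 75106 autosomal peaks at time point 1 and 109496 ± 59469 at time point 2 (SD, n = 6). Persons with increased PTSD had 173032 ± 65283 and 119068 ± 50145, and persons with persistent PTSD 72880 ± 44683 and 102502 ± 58107 (n = 4 each). The mean log2 change was -0.27 in controls, where the number rose in 2 of 6 persons (exact p 0.594), and 0.13 without control replicate 12. It was -0.59 in increased PTSD, with a rise in 1 of 4 (exact p 0.375), -1.04 without increased replicate 3 and -0.26 without increased replicate 13. It was 0.65 in persistent PTSD, with a rise in 2 of 4 (exact p 0.5), and 0.0631 without persistent replicate 6, who had the smallest list. At time point 1, lists were 2.80 times as large (ratio of geometric means) in increased as in persistent PTSD (exact p 0.0571, adjusted 0.791 over 12 comparisons). Without persistent replicate 9 that log2 difference rose from 1.49 to 1.83 and reached the smallest exact p of that design, 0.0286, and without persistent replicate 6 it fell to 0.90 (exact p 0.114). No other comparison of list sizes between groups or of their changes had an exact p under 0.171 with all persons included. Across the 14 libraries of a time point, list size was not detectably related to sequencing depth, with a Pearson r of 0.43 at time point 1 (permutation p 0.129, adjusted 0.147 over 8 relations, Spearman rho 0.38, r without the 2 most extreme libraries 0.42) and 0.17 at time point 2 (permutation p 0.562, adjusted 0.562, rho 0.22, r without 2 libraries 0.03). It went with the covered length of the kept peaks, with r of 0.83 (permutation p 2e-04, adjusted 0.000533, rho 0.93, r without 2 libraries 0.87) and 0.89 (permutation p 1e-05, the smallest possible, adjusted 8e-05, rho 0.91, r without 2 libraries 0.87). The kept lists were therefore matched in number but not in length, which ran from 6.64 to 16.6 Mb.

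**Figure D2:**
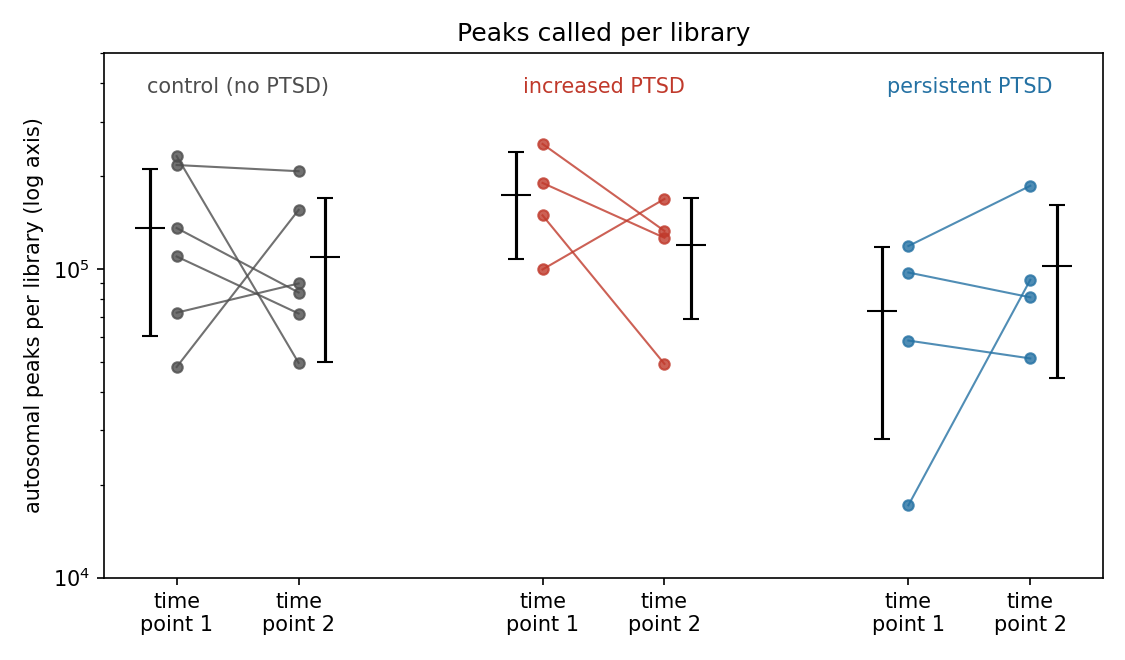
Autosomal peaks per library on a log axis, with a line joining the 2 libraries of a person and bars for the mean and SD of each group. Lists ran from 17142 to 253806 peaks, and the groups overlapped at both time points.

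On average, the peak map of a person was more like that person's own map at the other time point than like the maps of others in the same group. The Jaccard index was 0.154 within persons and 0.140 between persons of a group, a difference of 0.0138 (exact permutation p 0.000147 over 414720 pairings, n = 14 persons). The time point 1 library of control replicate 12 was less like its own time point 2 library (0.137) than like those of others (mean 0.160). For increased replicate 13 it was 0.151 against 0.156, and the remaining persons went the other way. For 10 of the 14 persons, the time point 2 library of the group with the highest index was their own; this was so for 4 of 14 with the share of peaks overlapping by 50%, and for 4 of 14 with all deposited peaks. The difference was 0.0126 in controls (exact p 0.0375), 0.0101 in increased PTSD and 0.0194 in persistent PTSD (exact p 0.0417 each, the smallest possible with 24 pairings). In controls the exact p was 0.275, 0.075, 0.05, 0.2 and 0.183 without replicate 1, 3, 8, 10 and 11 in turn. With 3 persons left in a PTSD group the smallest possible exact p is 0.167, so leaving out a person tests nothing there. It was found in the kept lists and not with all deposited peaks, where it was 0.00498 over all groups (exact permutation p 0.638).

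**Figure D3:**
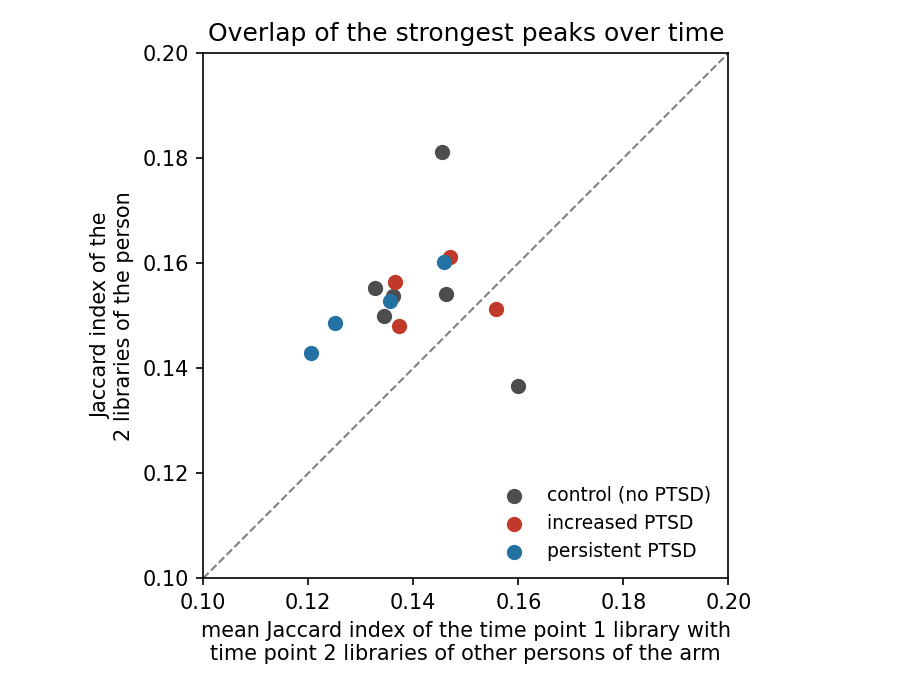
Jaccard index of the 2 libraries of each person against the mean index of that person's time point 1 library with time point 2 libraries of other persons of the group; the dashed line marks equality. The means over the 14 persons were 0.154 within and 0.140 between persons.

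How far the map of a person moved between the time points did not differ between the groups by more than between persons. The index within persons was 0.155 ± 0.0145 in controls (SD, n = 6), 0.154 ± 0.00574 in increased PTSD and 0.151 ± 0.00724 in persistent PTSD (n = 4 each). The differences were smaller than the spread between persons, with exact permutation p of 0.905 for increased against control, 0.657 for persistent against control and 0.571 for increased against persistent PTSD (adjusted 0.905 each). The sign of these differences changed with the peak lists used. The index also followed list size. Across the 14 libraries of a time point, the mean index of a library to the others rose with its number of peaks, with r of 0.86 (permutation p 6e-05, adjusted 0.00024, rho 0.80, r without 2 libraries 0.78) and 0.84 (permutation p 3e-04, adjusted 0.0006, rho 0.77, r without 2 libraries 0.79), so it does not measure movement alone.

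The next comparisons ask what changed from time point 1 to time point 2 in each group. In control persons, the window on chromosome 2 from 239100001 to 239200000 lost most of its coverage. It held 1438 bp ± 311 of kept peaks at time point 1, in 6 of 6 persons, and 65.3 bp ± 160 at time point 2, in 1 of 6 (SD, n = 6; log2 change -2.75, limma adjusted p 0.381). On chromosome 16, the window from 87900001 to 88000000 fell from 3304 bp ± 1247 to 760 bp ± 844 (log2 change -2.35, adjusted p 0.381). On chromosome 9, the window from 137800001 to 137900000 rose from 299 bp ± 568, in 2 of 6 persons, to 1952 bp ± 1518, in 6 of 6 (log2 change 2.44, adjusted p 0.991). None of the 12254 windows passed the limma threshold. At an unadjusted p under 0.05 there were 543, of which 222 rose (194 of 370 in lists matched on covered length). The region on chromosome 4 from 2323414 to 2324227 was gained in every control person and that on chromosome 16 from 87594751 to 87596078 was lost in every one, which is 1 region each way; 39 of the 64 orders of the time points gave as many. With each single control left out, between 1 and 6 regions were gained and between 2 and 9 lost in all who remained. These counts can only stay or rise when a person is left out, since fewer persons must change alike.

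In increased PTSD, coverage of the kept peaks fell more often than it rose, whereas in lists matched on covered length it rose more often. On chromosome 6, the window from 13700001 to 13800000 fell from 2204 bp ± 904 in 4 of 4 persons to 87.2 bp ± 174 in 1 of 4 (SD, n = 4; log2 change -3.16, limma adjusted p 0.364). On chromosome 7, the window from 156800001 to 156900000 fell from 1337 bp ± 524 in 4 of 4 persons to none in all 4 (adjusted p 0.364). In the other direction, the window on chromosome 1 from 145900001 to 146000000 held no kept peak in any person at time point 1 and 1007 bp ± 321 in 4 of 4 at time point 2 (adjusted p 0.487). None of the 12254 windows passed the limma threshold with all persons included, and 871 had an unadjusted p under 0.05, of which 189 rose; after the median of each library was subtracted, 383 of 813 rose, and in lists matched on covered length 303 of 464. Without increased replicate 3, 1 window passed, on chromosome 8 from 7100001 to 7200000, with a log2 change of -3.06. With all 4 persons included it held 6.13 kb ± 7.63 at time point 1, in 4 of 4. At time point 2 it held 5.31 kb ± 10.3, in 2 of 4, so the persons of this group were split there. All 4 persons lost 57 regions and gained 18. Among the lost were chromosome 11 from 734368 to 737051 and from 71183977 to 71188904, and among the gained was chromosome 17 from 16295719 to 16296636. As many losses came up in 2 of the 16 orders of the time points, and the highest count of another order was 62. The median log2 change over all tested windows was -0.16, in the direction of the smaller lists at time point 2. With each single person of this group left out, between 189 and 352 regions were lost and between 99 and 109 gained in all who remained. Such counts cannot fall when a person is left out.

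In persistent PTSD, coverage of the kept peaks rose more often than it fell, and less often in lists matched on covered length. On chromosome 5, the window from 137400001 to 137500000 held no kept peak in any person at time point 1 and 1170 bp ± 851 in 4 of 4 at time point 2 (SD, n = 4; limma adjusted p 0.988). On chromosome 7, the window from 75100001 to 75200000 rose from 272 bp ± 365 to 1770 bp ± 111 (log2 change 2.39, adjusted p 0.988). On chromosome 17, the window from 17600001 to 17700000 fell from 1530 bp ± 722 in 4 of 4 persons to 87.8 bp ± 176 in 1 of 4 (log2 change -2.62, adjusted p 0.988). None of the 12254 windows passed the limma threshold, and 473 had an unadjusted p under 0.05, of which 290 rose, against 273 of 488 with the library median subtracted and 144 of 335 in lists matched on covered length. All 4 persons gained 20 regions, such as chromosome 1 from 10736500 to 10739024, and lost 9, such as chromosome 16 from 22537992 to 22539318. As many gains came up in 6 of the 16 orders of the time points. With each single person of this group left out, between 86 and 149 regions were gained and between 70 and 130 lost in all who remained. Here too the counts cannot fall by construction.

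Whether the course over time differed between the groups was tested directly. On chromosome 11, the window from 44600001 to 44700000 moved in opposite directions. It rose in controls from 148 bp ± 168 to 1054 bp ± 584 (n = 6) and fell in increased PTSD from 1237 bp ± 597 to 198 bp ± 364 (n = 4; log2 difference of change -3.97, limma adjusted p 0.783). On chromosome 9, the window from 137800001 to 137900000 rose in controls and fell in persistent PTSD, from 1427 bp ± 1139 to 135 bp ± 156 (log2 difference -4.31, adjusted p 1.0). On chromosome 12, the window from 123900001 to 124000000 rose in increased PTSD from 295 bp ± 590 to 1864 bp ± 1612 and fell in persistent PTSD from 1490 bp ± 589 to 385 bp ± 305 (log2 difference 4.05, adjusted p 0.706). No window passed the limma threshold in any of the 3 differences. At an unadjusted p under 0.05 there were 709 windows for increased against control, of which 230 were higher in increased, 530 for persistent against control, of which 325 were higher in persistent, and 801 for increased against persistent PTSD, of which 190 were higher in increased. With the library median subtracted, 346 of 694, 294 of 534 and 343 of 734 were higher in turn, and with the library mean subtracted 331 of 691, 273 of 534 and 367 of 744. Lists matched on covered length reversed each split, to 253 of 429, 155 of 364 and 281 of 429. The median log2 difference over all tested windows was -0.14 for increased against control and -0.23 for increased against persistent PTSD.

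At time point 1, kept peaks covered less in increased PTSD than in controls in a block beside the centromere of chromosome 16. Between 32 and 34 Mb, a range chosen after its values were seen, the difference was -44.3 kb (exact p 0.00476), and with all deposited peaks it was -23.7 kb (exact p 0.286). Persistent PTSD, at 98.8 kb ± 27.0, lay nearer to increased PTSD (90.0 kb ± 14.9) than to controls (134 kb ± 15.1). On chromosome 16, the window from 33400001 to 33500000 held 9531 bp ± 1776 in controls (SD, n = 6) and 3740 bp ± 2315 in increased PTSD (n = 4; log2 difference -1.66, limma adjusted p 0.558), and that from 32700001 to 32800000 held 2805 bp ± 789 and 497 bp ± 352 (log2 difference -2.30, adjusted p 0.539). Of the 5 regions with a peak in all 6 controls and in no person with increased PTSD, 4 lay in this block, between 32198629 and 33739471; 102 of the 210 splits of these persons gave as many as 5 such regions, and the highest other count was 22. The reverse, a peak in all with increased PTSD and in no control, came up in 18 regions and in as many in 48 of the 210 splits. With each single person left out, the 5 became up to 18 and the 18 up to 122, counts that cannot fall by this step. On chromosome 4, the window from 38800001 to 38900000 was the reverse, with 1168 bp ± 908 in increased PTSD and no kept peak in any control or any person with persistent PTSD (adjusted p 0.382 against controls). No window passed the limma threshold. At an unadjusted p under 0.05 there were 847, of which 684 were higher in increased PTSD, and the median log2 difference over all tested windows was 0.17. With the library median subtracted, 376 of 796 were higher in increased PTSD, and in lists matched on covered length 183 of 424.

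Persistent PTSD differed from controls at time point 1 in windows on chromosomes 17 and 19, none past the limma threshold with all persons included. On chromosome 19, the window from 8800001 to 8900000 held 28139 bp ± 5176 in persistent PTSD (SD, n = 4) and 9856 bp ± 7327 in controls (n = 6; log2 difference 2.02, limma adjusted p 0.909). Increased PTSD stood near persistent PTSD there, at 23064 bp ± 9254. On chromosome 17, the window from 34500001 to 34600000 held 4056 bp ± 3440 in persistent PTSD and 11963 bp ± 2413 in controls (log2 difference -2.38, adjusted p 0.909). Increased PTSD lay between them, at 7.70 kb ± 2.70. That window held a kept peak in 3 of 4 persons with persistent PTSD and in 6 of 6 controls. The person without one enters at the pseudocount of 200 bp, which widens the log2 difference. With limma, 0 windows passed the threshold, and 581 had an unadjusted p under 0.05, of which 222 were higher in persistent PTSD (307 of 623 with the library mean subtracted and 316 of 443 in lists matched on covered length). After the median of each library was subtracted, 3 windows passed, these 2 and that on chromosome 17 from 36300001 to 36400000, with a log2 difference of -2.19. The last also held a kept peak in 3 of 4 persons with persistent PTSD. Its coverage was 8.37 kb ± 6.29 in persistent PTSD, 13.9 kb ± 4.98 in increased PTSD and 19.4 kb ± 6.36 in controls.

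In the kept lists, increased PTSD was covered more than persistent PTSD at time point 1 in most windows that differed, and the reverse held in lists matched on covered length. On chromosome 4, the window from 1300001 to 1400000 held 12610 bp ± 5532 in increased and 2456 bp ± 919 in persistent PTSD (SD, n = 4 each; log2 difference 2.23, limma adjusted p 0.359). On chromosome 18, the window from 12400001 to 12500000 held 3270 bp ± 1682 and 302 bp ± 207 (log2 difference 2.80, adjusted p 0.359). On chromosome 2, the window from 121500001 to 121600000 was the reverse, with 101 bp ± 202 and 1295 bp ± 564 (log2 difference -2.42, adjusted p 0.372). With all persons included, 0 windows passed the limma threshold, and 1105 had an unadjusted p under 0.05, of which 896 were higher in increased PTSD, against 556 of 1004 with the library median subtracted and 163 of 582 in lists matched on covered length. The median log2 difference over all tested windows was 0.25. Without increased replicate 3, 2 windows passed, on chromosome 16 starting at 2200001 and on chromosome 18 starting at 77200001, with log2 differences of 2.70 and 2.35. Peaks in all 4 persons with increased and no person with persistent PTSD came up in 72 regions and the reverse in 22, and 3 of the 70 splits of these persons gave as many as 72 and 46 as many as 22. With each single person left out, the 72 became up to 303 and the 22 up to 108, counts that cannot fall by this step.

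At time point 2, kept peaks again covered less of the block on chromosome 16 in increased PTSD than in controls. These are the same persons and the range chosen after its values were seen, so this is no independent repeat. The difference was -50.2 kb (exact p 0.0143), and with all deposited peaks -44.4 kb (exact p 0.0952). Persistent PTSD stood between them, at 99.4 kb ± 20.1. On chromosome 16, the window from 32300001 to 32400000 held 9578 bp ± 1669 in controls (SD, n = 6), 3439 bp ± 2747 in increased and 6476 bp ± 2417 in persistent PTSD (n = 4 each; log2 difference of increased from control -1.91, limma adjusted p 0.519). The windows from 32600001 to 32700000 and from 33300001 to 33400000 had log2 differences of -2.52 and -1.33. The region from 32363030 to 32363504 had a peak in 6 of 6 controls at both time points and in no person with increased PTSD at either, and in 3 and 2 of 4 persons with persistent PTSD. On chromosome 2, the window from 239100001 to 239200000 was higher in increased PTSD, at 1752 bp ± 857 against 65.3 bp ± 160 (log2 difference 2.90, adjusted p 0.519). No window passed the limma threshold with all persons included and 571 had an unadjusted p under 0.05, of which 349 were higher in increased PTSD (287 of 583 with the library median subtracted). After the median of each library was subtracted, 4 windows passed. They were that from 32300001 on chromosome 16 (log2 difference -1.97), chromosome 8 from 7100001 to 7200000 (-2.95), and chromosome 19 from 8800001 to 8900000 (1.70) and from 48400001 to 48500000 (-1.59). Without increased replicate 3, the window on chromosome 8 passed without that step, with a log2 difference of -4.43. With all persons included that window held 5.31 kb ± 10.3 in increased PTSD, in 2 of 4 persons. In controls it held 9.05 kb ± 7.82, in 6 of 6. Peaks in all controls and in no person with increased PTSD came up in 12 regions, and 6 of the 210 splits of these persons gave as many. The reverse came up in 13 regions, and 73 of the 210 splits gave as many. With each single person left out, the 12 became up to 28 and the 13 up to 68, counts that cannot fall by this step.

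**Figure D4:**
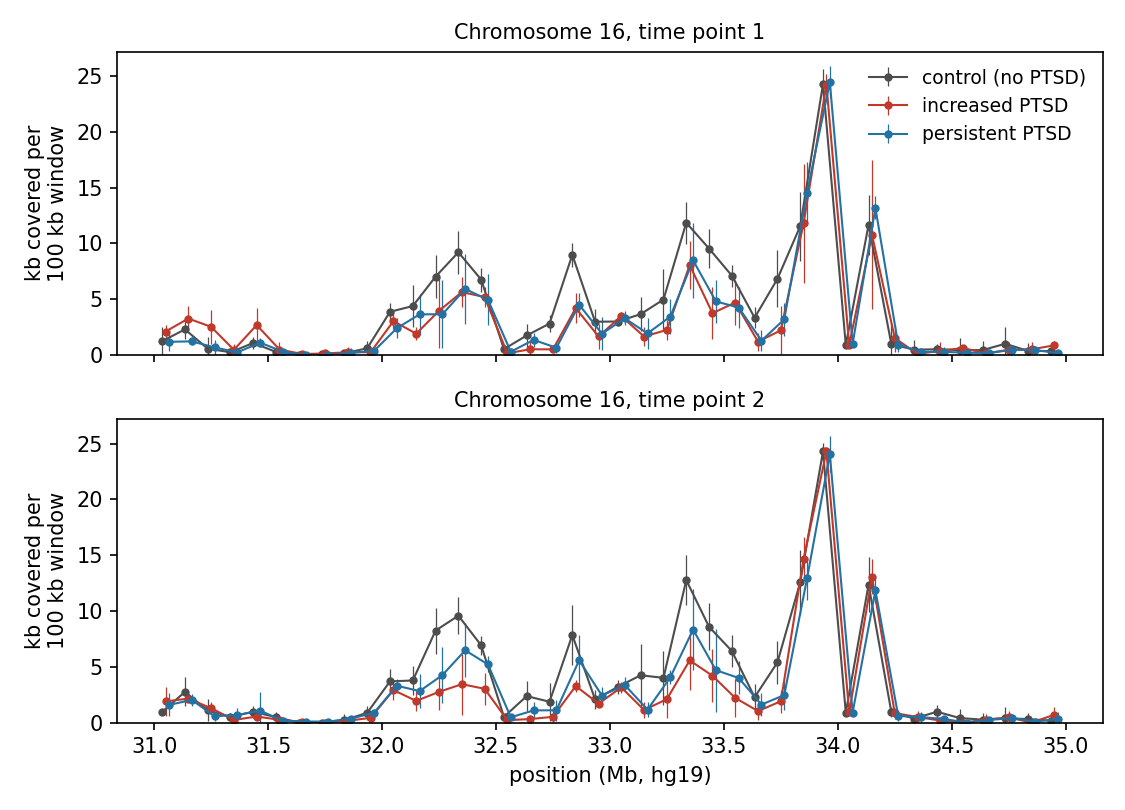
Base pairs covered by kept peaks in 100 kb windows of chromosome 16 between 31.0 and 35.0 Mb (hg19), as the mean and SD of each group at each time point. Between 32 and 34 Mb the control means lay above those of increased PTSD in most windows, and the highest window, starting at 33900001, was level in all groups.

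Persistent PTSD differed from controls at time point 2 again on chromosomes 19 and 17, in the same persons, so this is no independent repeat. Increased PTSD stood nearer to persistent PTSD than to controls in the windows given here. On chromosome 19, the window from 8800001 to 8900000 held 26406 bp ± 5867 in persistent PTSD (SD, n = 4) and 9414 bp ± 6825 in controls (n = 6; log2 difference 2.17, limma adjusted p 0.644). On chromosome 17, the window from 36300001 to 36400000 held 8804 bp ± 5998 and 20134 bp ± 4807 (log2 difference -1.72, adjusted p 0.644). Increased PTSD held 21.7 kb ± 9.60 in the window on chromosome 19 and 11.2 kb ± 3.64 in that on chromosome 17. No window passed the limma threshold with all persons included, and 560 had an unadjusted p under 0.05, of which 317 were higher in persistent PTSD. The window on chromosome 19 passed without control replicate 8 (log2 difference 2.37) and without increased replicate 5 (2.17). After the median of each library was subtracted, the same 3 windows passed as at time point 1, with log2 differences of 2.13 on chromosome 19 and of -2.11 and -1.75 on chromosome 17. In that from 34500001, again 3 of 4 persons with persistent PTSD held a kept peak. Its coverage was 4.66 kb ± 4.08 in persistent PTSD, 5.27 kb ± 1.11 in increased PTSD and 11.1 kb ± 4.39 in controls.

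Between increased and persistent PTSD at time point 2, the window on chromosome 14 from 23100001 to 23200000 held 2006 bp ± 1186 and 141 bp ± 282 (SD, n = 4 each; log2 difference 2.78, limma adjusted p 0.951). On chromosome 1, the window from 156200001 to 156300000 held no kept peak in the 4 persons with increased and 1325 bp ± 243 in persistent PTSD (adjusted p 0.951). The region on chromosome 5 from 177951823 to 177952859 had a peak in all 4 persons with increased and in no person with persistent PTSD at both time points. The limma threshold was passed by 0 windows with all persons included, and 552 had an unadjusted p under 0.05, of which 300 were higher in increased PTSD (149 of 347 in lists matched on covered length). Without increased replicate 3, the window on chromosome 8 from 7100001 to 7200000 passed, with a log2 difference of -4.12.

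Presence of a peak per region gave no difference between groups past the threshold with Fisher's exact test. At an unadjusted p under 0.05 there were 438 regions at time point 1 for increased against control, of which 372 were more often present in increased PTSD, 264 for persistent against control and 94 for increased against persistent PTSD. At time point 2 there were 338, 270 and 58. Leaving out each person in turn gave 298 to 701, 195 to 439 and 94 to 345 at time point 1. At time point 2 it gave 255 to 492, 200 to 418 and 58 to 155. The 701 came without control replicate 12 and the 345 without increased replicate 3. Between the PTSD groups, only a peak in all of one and none of the other reaches p under 0.05 with Fisher's exact test. Leaving out a person therefore cannot lower those counts. With all deposited peaks there were 5113, 2851 and 4516, and 2242, 1503 and 409. For persistent PTSD against controls at time point 1 this took the share more often present in persistent PTSD from 190 of 264 to 156 of 2851. With 4 against 6 persons, group size alone favours the smaller group in the kept lists. Other splits of the persons at time point 1 show this for increased against control. Their median was 12 regions with a peak in all of the 4 and none of the 6, and 4 the reverse. For persistent against control these medians were 11 and 3. These splits counted only regions in all of one group and none of the other, not those at an unadjusted p under 0.05. The 372 of 438 and the 190 of 264 were thus not set against splits and are not read as a direction. The smallest exact p that a region can reach is 0.00476 with 4 against 6 persons and 0.0286 with 4 against 4, and the smallest adjusted p was 1.0 in each comparison, over 83360 to 100017 regions.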

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

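Every group of 4 to 6 libraries was searched for a library that stood far apart from the others, and every pair of groups for a difference in the change over time of a library measure. These searches tested 69 groups and found 2 libraries, where chance alone gives 3.45 at 1 in 20, and 33 differences of change and found 1, where chance alone gives 1.65. They concern depth and length of the peak lists, and no explanation of them was tested.

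The library of persistent PTSD replicate 1 at time point 1 held 8.76 M filtered tags, and the other 3 libraries of that group and time point held between 6.82 M and 7.08 M. The library of persistent PTSD replicate 9 at time point 2 stood apart in the covered length of its strongest 17142 peaks, 12.5 Mb against 8.29 to 8.81 Mb in the others. The number of 17142 was set by the smallest list, that of persistent PTSD replicate 6 at time point 1, and the next smallest held 48096 peaks.

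The change of depth over time stood out between persistent PTSD and controls, without adjustment. Filtered tags fell by 1.02 M on average from time point 1 to time point 2 in persistent PTSD (n = 4) and rose by 0.338 M in controls (n = 6), a difference of -1.36 M (exact permutation p 0.0286).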

How the results depend on the processing

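Windows of 20 kb, subtraction of the library mean, length-matched lists in the comparison of libraries, and the mean of both time points with all its settings were chosen after the results were seen, as were all counts over other splits of the persons. The comparisons of gene lists and promoter regions were not run, since the annotation at hand is of another build.

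The count of windows past the limma threshold was 0 in the 12 comparisons and rose above 0 in some settings. With no filter on low values it was 7, 5 and 12 at time point 1 for increased against control, persistent against control and increased against persistent PTSD, and 2 at time point 2 for persistent against control. With the library median subtracted it was 3 at time point 1 and 3 at time point 2 for persistent against control, and 4 at time point 2 for increased against control; with the library mean subtracted it was 3, 3 and 5. Without the person who had the smallest list, and with the next smallest list setting the size, it was 1 at time point 1 for increased against persistent PTSD and 3 at time point 2 for persistent against control. With all deposited peaks and list size as a covariate it was 1 at time point 1 for persistent against control, and with 20 kb windows 1 at time point 1 for increased against persistent PTSD. The mean of both time points gave 0 in the 3 comparisons of groups with 778, 641 and 901 windows at an unadjusted p under 0.05. With no filter 15, 8 and 11 windows passed, and robust variances gave 1 for persistent against control and 1 for increased against persistent PTSD. The cause of these changes was not tested. Windows of 1 Mb and peak counts per window gave 0 in all 12 comparisons, as did leaving out the windows near the longest peak-free stretch. Subtraction of the library median also reduced the excess of one direction at an unadjusted p under 0.05. The share that rose in increased PTSD went from 189 of 871 windows to 383 of 813, and at time point 1 the share higher in increased PTSD went from 684 of 847 to 376 of 796 against controls and from 896 of 1105 to 556 of 1004 against persistent PTSD. That follows from the construction of this step, which sets the overall level of every library equal. Lists matched on covered length reversed these 3 splits, to 303 of 464, 183 of 424 and 163 of 582, as they did for the mean of both time points, from 576 of 778 higher in increased PTSD to 195 of 467 against controls and from 701 of 901 to 142 of 511 against persistent PTSD. From 250 of 641 the windows higher in persistent PTSD than in controls went to 290 of 464. All deposited peaks, unmatched in number, gave 8 of 1669, 1110 of 1112 and 10508 of 10513 for the 3 splits, and 1058 of 1070, 5 of 1116 and 6721 of 6721 for the mean of both time points in increased against control, persistent against control and increased against persistent PTSD. No replicate block gave 0 windows for each change and each difference of change, as did a random effect for the person. Leaving out each person in turn gave 0 to 1 for the change in increased PTSD, 0 to 2 at time point 1 for increased against persistent PTSD, 0 to 1 for each comparison at time point 2, and 0 to 1 and 0 to 3 for the mean of both time points in increased and in persistent PTSD against controls. The 3 came without persistent replicate 9, and the others came without increased replicate 3 or, for persistent PTSD against controls at time point 2, without control replicate 8 or increased replicate 5.

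The real count of windows was 0 throughout, so every other split of the same persons had to give as many and chance cannot be excluded. These were 32 of 32 orders of the time points for controls (highest other 31) and 100 of 100 splits in the comparisons with controls. The highest other counts were 171 and 21 for the difference of change, 63 and 13 at time point 1, 4 and 90 at time point 2, and 3 and 10 for the mean of both, for increased and persistent PTSD in turn. Between increased and persistent PTSD it was 35 of 35 splits, with 0, 2, 3 and 3 as the highest other. For the change in increased and in persistent PTSD, 8 of 8 orders gave 0, too few for a share under 0.05. Splits that call up to 171 windows point to a structure of the libraries other than the groups, or to windows that vary together; neither was tested.

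The number of peaks at time point 2 in increased against control reversed from 0.154 to -0.0486 on the log2 scale under the stricter peak limit of 5. Leaving out each person in turn gave log2 values from -0.66 to 0.13 for the change in controls, 0.90 to 1.83 for increased against persistent PTSD at time point 1, -0.0570 to 0.53, -0.43 to 0.19 and -0.0387 to 0.62 for the 3 comparisons at time point 2, -0.78 to 0.0652 for the difference of change of increased from control, and -0.72 to 0.14 for the covered length in controls.

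The mean likeness of the libraries of a person stayed past its test over all groups in every setting but all deposited peaks, where the difference was 0.00498 (exact p 0.638), -0.00181 in controls, 0.00116 in increased and 0.0190 in persistent PTSD; the cause was not tested. Leaving out each person gave 0.00933 to 0.0182, 0.00812 to 0.0120 and 0.0175 to 0.0244 in turn. The comparison of likeness over time between groups, with no difference past its test, reversed for persistent against control (0.00290) and increased against persistent PTSD (-0.0195) with lists of 8571 peaks, and for increased against control with all deposited peaks (0.0467), the 50% overlap (0.00775) and length-matched lists (0.000424). Leaving out each person gave -0.00464 to 0.00428 for increased and -0.00766 to 0.00125 for persistent PTSD against controls.

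Counts of regions gained and lost in every person changed with the lists. With at least 50% of a region covered they were 0 and 0 in controls, 5 and 20 in increased and 1 and 1 in persistent PTSD. With all deposited peaks, unmatched in number, they were 0 and 19 in controls, 26 and 1571 in increased and 379 and 22 in persistent PTSD. As many as 1571 losses came up in 2 of the 16 orders of the time points, with 4006 the highest other count. For 379 gains it was 4 of 16, with 684 the highest other. Under the stricter peak limit, also unmatched in number, increased PTSD gained 6 and lost 851, and persistent PTSD gained 56 and lost 10. As many as 851 losses came up in 2 of 16 orders (highest other 2467) and 56 gains in 3 of 16 (highest other 155). Lists matched on covered length, which turned the split of windows in increased PTSD, were not run for regions. Leaving out each person gave 1 to 6 gained and 1 to 9 lost in controls, 18 to 109 and 57 to 352 in increased, and 20 to 149 and 9 to 130 in persistent PTSD.

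At this depth of 5.54 M to 9.03 M filtered tags the lists decide what can be seen. A simulated log2 difference of 2 between increased PTSD and controls at time point 2 was recovered in 31.2% of windows and one of 3 in 84.8%, so smaller differences would mostly be missed.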

Other observations

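The observations and tests in this part were all chosen after the results were seen.

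In a small set of windows, persons differed from one another by a similar amount at both time points. Within groups, the covered length of a window at time point 1 was correlated over the 14 persons with that at time point 2. In 90 of the 6361 windows covered in at least 14 libraries the correlation exceeded 0.8, while the median over all windows was 0.0308. Of the 90 windows, 31 lay beside another. With gaps of up to 1000 kb joined, the groups with the most windows were on chromosome 15 from 20300001 to 22700000 (9 windows), chromosome 5 from 68900001 to 70600000 (7), chromosome 8 from 7100001 to 7900000 (5) and chromosome 17 from 34400001 to 34900000 (4). The highest correlations were 0.993 on chromosome 4 from 52600001 to 52700000, 0.989 on chromosome 11 from 93900001 to 94000000, 0.983 on chromosome 17 from 36300001 to 36400000 and 0.981 on chromosome 19 from 8800001 to 8900000. Within 2 Mb of the longest peak-free stretch lay 21.1% of the 90 windows and 5.19% of all.

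Chance pairing of libraries gave at most 25 such windows in 99 other pairings, so 1 of 100, the real one, gave as many. The list size of a person's libraries cannot be the whole cause, since 60 windows remained above 0.8 after its trend was removed, against at most 22 in other pairings. With all deposited peaks 39 windows exceeded 0.8, fewer than the 380 of the highest other pairing, and with list size as a covariate 84 against 62. A candidate explanation is that segments of DNA whose number of copies, or whose methylation, differs between persons are captured to a different extent. Such segments would span neighbouring windows, and 31 of the 90 windows lay beside another, against at most 12 in 1000 random sets of as many windows. The sets were matched in number of windows. The 90 lay near the longest peak-free stretch more often than all windows (21.1% against 5.19%), which could give neighbours by itself. This test does not separate copies from methylation or from such clustering, and an allele that maps poorly to the reference would span neighbours too.

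A group difference in these windows recurs at both time points by construction, since persons keep their levels there. For increased against control, 10 of the 90 windows and 29 of the others had an unadjusted limma p under 0.05 with the same sign at both time points; it was 11 and 15 for persistent against control, and 8 and 20 for increased against persistent PTSD. Of the 7 windows that passed the threshold once the library median or mean was subtracted, 6 were among the 90, including those on chromosome 19 from 8800001 and on chromosome 17 from 34500001 and 36300001. Among the 174 windows covered as much as these 7, 33 were among the 90. Persons dealt to the groups by chance may give such differences. Counted with the ordinary pooled spread of each window in place of limma's, the real groups had 6 such windows among the 90 for increased against control, 0 for persistent against control and 1 for increased against persistent PTSD. As many came up in 8 of 210, 210 of 210 and 58 of 70 splits of the persons, with 9 the highest other and 1 the median in each. The first share is under 0.05 only without adjustment for the 3 comparisons, so chance stays open there, as it does for increased against persistent PTSD. For persistent against control every split had to reach a count of 0, so the recount tests nothing. The 11 windows counted there with limma were not set against splits, and chance was not tested for them. The other 6271 windows had 26, 14 and 21 such windows, reached in 6 of 210, 54 of 210 and 8 of 70 splits, against medians of 9, 11 and 11. After adjustment for the 3 comparisons chance stays open there as well.

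A second observation was the block on chromosome 16 between 32 and 34 Mb. Kept peaks covered 134 kb ± 15.1 in controls at time point 1 and 131 kb ± 22.6 at time point 2 (SD, n = 6), 90.0 kb ± 14.9 and 80.4 kb ± 17.9 in increased PTSD, and 98.8 kb ± 27.0 and 99.4 kb ± 20.1 in persistent PTSD (n = 4 each). Controls and increased PTSD did not overlap at either time point, with exact permutation p of 0.00476, the smallest possible, and 0.0143. The size of the peak lists cannot be the whole cause, since the differences were -47.1 kb and -51.8 kb after its trend was removed, against -44.3 kb and -50.2 kb before. The exact p was then 0.00476 at both time points, on a range chosen for its difference. With all deposited peaks the differences were -23.7 kb and -44.4 kb, with exact p of 0.286 and 0.0952. A chance maximum of many windows stays open, because 145 of the 210 splits of these persons had some window in the genome at least as extreme as the most extreme of the block. Lasting differences between persons stay open as well, since the covered length at both time points was correlated within groups (Pearson r 0.702, permutation p 0.00576, Spearman rho 0.644, r without 2 persons 0.671, n = 14). A tie to PTSD is a possible biological explanation, and it was not tested apart from these. Copies or methylation that differ between persons, named above, are another, since all lists share the same input. The values do not single out increased PTSD, since it differed from persistent PTSD by -8.83 kb and -19.0 kb (exact p 0.686 and 0.229). Persistent PTSD differed from controls by -35.4 kb and -31.2 kb in turn (exact permutation p 0.0286 and 0.0714). With all deposited peaks, persistent PTSD differed from controls by -54.6 kb and -32.2 kb (exact permutation p 0.0476 and 0.186). At time point 1 that was a larger gap than that of increased PTSD.

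The share of kept peaks within 2 Mb of the longest peak-free stretch was lower in increased PTSD than in controls at both time points. That zone takes in part of the block on chromosome 16, such as the window from 33700001, so the observations overlap and are not independent. The whole block held on average 169 and 161 of the 17142 kept peaks in controls at time points 1 and 2. In increased PTSD it held 84.8 and 89.0, too few fewer to make up the whole difference in share. The share without the block was not computed. The share was 7.12% ± 0.602 against 8.11% ± 0.523 at time point 1 and 7.75% ± 0.210 against 8.48% ± 0.469 at time point 2 (SD, n = 4 and 6, exact permutation p 0.0286 each, adjusted 0.837 over 288 comparisons). With all deposited peaks the differences were -0.580 and -0.361 percentage points, with exact p of 0.295 and 0.5.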
